A study of Homo sapiens with 23 samples.

How the data were processed

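The values came from the deposited table of raw bead array signals, which per the file headers gives for each of 23 arrays a signal intensity per probe, without normalization, and a detection p-value. The deposited series table holds quantile-normalized intensities on a linear scale and was used as an alternative. No method of analysis, probe sequence or genome build was given in the sources used here, so no coordinates are given. Per the labels, biotin-labelled RNA copies were made from total RNA of 10 to 50 mg of frozen tissue.

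Signals were background corrected by the normal-exponential method with control intensities inferred from the detection p-values, an offset of 16 was added, and values were quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). A probe was tested if its detection p-value was under 0.01 on at least 5 arrays, which 15942 of 48803 probes (32.7%) met. Arrays whose code shares its first part were treated as repeat arrays of 1 specimen, and each specimen's value was its least-squares mean from a fit of specimen plus array set without the specimen number as a block, so that the combination specimen with 1 array was adjusted for its set. The 12 specimens of 4 groups entered 1 limma fit with empirical Bayes at its defaults (residual degrees of freedom 8, prior 5.62). P-values were adjusted by the Benjamini-Hochberg method over the 15942 probes of each of 7 comparisons, of which the 3 against untreated tumours share their controls. From 14272 to 15564 probes were detected per array, and the number of specimens limits the precision. The fold where a group was not detected on any of its arrays was computed against the lowest normalized signal among detected probes of each array and is given as at least that fold, and a departure from the sum that holds such a group was limited in the same way.

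Gene names came from an annotation table of the platform's probes, held here in part, which listed 28111 probes and left 20692 unlisted, and 13 listed probes with several genes were left unnamed. Of 28098 probes with 1 gene, 28059 matched the RefSeq gene table (assembly GRCh38.p14, used for names only) by gene number. Among tested probes 2367 had no name. A gene was represented by its tested probe with the highest mean, which gave 10448 genes. Counts of genes are over these representatives.

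The choices here, the 22 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule named, for each comparison with untreated tumours, up to 10 called genes with the largest rise and 10 with the largest fall whose sign held in each array set alone, and up to 5 each way between treatments. Where fewer than 5 passed in a direction, the smallest p-values filled it up to 5 as values without a call. ERBB2, ERBB3, EGFR, CDKN1A, CDKN1B, CCND1 and MKI67 were given in each comparison with untreated tumours, as were up to 4 members with the smallest p-value of each list described. Other names in the text were chosen after their values were seen where this is said.

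Gene lists with at least 3 measured members (19 of 22) were tested with camera in limma, two-sided and with a preset correlation between genes of 0.01, and adjusted over 57 tests against untreated and 76 between treatments. Each was also tested with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes. Of 21 list calls against untreated, 0 held with an estimated correlation and 1 by fry (epithelial genes with the combination). Of 32 calls between treatments 0 held with either. The endothelial, red cell and muscle lists had 1 measured member each and were not tested as lists. ERBB3, CDKN1A, GADD45A and CXCL8 belong to more than 1 list. Overlaps of calls were compared with 100 simulations of unchanged groups that share their controls. The alternatives tried were other filters, normalizations and background corrections, the deposited normalized values, all arrays as values, each array set alone, plain means of arrays, other variance priors, specimen weights, fits of only the groups compared, the specimen number as a block, leaving out each specimen and, chosen after seeing the data, leaving out combination array 2_2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

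The steps after normalization and filtering were first run on simulated log2 values of 15942 probes, drawn independently of each other, with known changes. Background correction, normalization and the filter were not simulated. With 1.5-fold changes, 62% were recovered for trastuzumab against untreated, 57% for pertuzumab, 58% for the combination, 54% and 47% for the combination against trastuzumab and pertuzumab, 55% between the antibodies and 13% for the departure from the sum. With 2-fold changes the shares were 94%, 93%, 98%, 99%, 94%, 94% and 63% in the same order. Each comparison held 100 probes changed at each fold, and the shares were not computed for other numbers of changed probes. From 1 to 8 unchanged probes were called per comparison. Among unchanged lists tested with camera, 1 was called in trastuzumab against pertuzumab and none in the other comparisons. Since the simulated probes were independent, this does not tell how often camera calls unchanged lists of correlated genes.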

Results

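The data were gene expression arrays of human ovarian cancer xenografts. Per the labels, fragments of tumours established from SKOV3, an ovarian cancer cell line known for extra copies of the receptor gene ERBB2 (HER2), were grown under the skin of nu/nu mice, which lack T cells. The growth protocol also named fragments of primary ovarian tumours as a possible source, while the labels stated the line of every sample as SCOV3. Mice were left untreated or received trastuzumab at 20 mg/kg, pertuzumab at 20 mg/kg, or 20 mg/kg of each, and tumour tissue was taken after 4 days. Trastuzumab and pertuzumab are antibodies to different parts of the HER2 protein, and pertuzumab binds the part through which HER2 pairs with other HER receptors. The study title states its aim as the molecular response to each antibody and to their combination.

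The 23 arrays came from 12 specimens, taken from the first part of each array's code, with 3 specimens per group and a second array for 11 of them. The untreated, trastuzumab and pertuzumab groups had 6 arrays each and the combination group had 5. Of the 48803 probes, 14272 to 15564 were detected per array in the untreated group, 14874 to 15370 with trastuzumab, 14785 to 15082 with pertuzumab and 14816 to 15302 with the combination. The mean signal per array ran from 208 to 365 in arbitrary units. Across probes, which are not independent replicates, repeat arrays of a specimen correlated at a median r of 0.51 after removal of group and array set means, and 20 of 22 arrays matched their own repeat best among the arrays of their group in the other set. Agreement was low for pertuzumab specimen 3 (r = 0.07) and combination specimens 1 (0.13) and 2 (−0.12). Each specimen was counted once (n = 3 per group), as fixed before the data were examined, and this number limits the precision of every value. The p-values measure the spread between these specimens alone. Values below are log2 differences ± SE from limma, and a gene was called at an adjusted p under 0.05.

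The first comparison set trastuzumab against no treatment. KRT5 and KRT16, keratins of layered epithelia, rose 3.79-fold and 2.48-fold with trastuzumab (1.92 ± 0.35 and 1.31 ± 0.17, n = 3 per group). KRT5 was near the threshold (adjusted p = 0.0485 by limma). It stayed called in 1 of 6 fits that left out a specimen, and KRT16 in 6 of 6. LY6D, a surface protein of keratinocytes, rose at least 2.67-fold and DSG3, a cadherin of desmosomes, at least 1.63-fold, both from a level not detected on any untreated array. KLK11, a secreted serine protease, rose by 1.80 ± 0.28, ANXA8, a calcium-dependent membrane-binding protein with a near-identical gene copy that its probe is not known to tell apart, by 1.66 ± 0.18, and LFNG, which modifies Notch receptors, by 1.25 ± 0.22. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 1.89-fold (0.92 ± 0.17, adjusted p = 0.0485). DAPL1 (1.47 ± 0.19), ADIRF (1.497 ± 0.25) and CLCA2 (1.40 ± 0.23) rose as well. No gene was called lower. The values nearest to a call were those of HMGA2, a chromatin protein (at least 1.21-fold lower, adjusted p = 0.0516), and BRINP3 (at least 1.18-fold lower), both not detected on any trastuzumab array, of INSIG1 (-0.67 ± 0.15), of NCEH1 (-0.43 ± 0.10) and of ANLN (-0.59 ± 0.13). ERBB2 itself (0.09 ± 0.19), ERBB3 (0.46 ± 0.14), EGFR (0.05 ± 0.20), CDKN1B (-0.04 ± 0.11), CCND1 (-0.20 ± 0.20) and the proliferation marker MKI67 (-0.32 ± 0.19) were not called.

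In all, 20 of 10448 genes were called with trastuzumab, all higher. An unadjusted p under 0.05, which chance gives about 5% of genes in any comparison, was found for 703. For each of the 20, all 3 treated specimens lay above all 3 untreated ones, a separation in this direction that chance gives 5% of genes and that 412 of 10448 genes showed. In either direction the share of all genes was 8.24%, against 10% by chance. The count was 13 within array set 1 and 10 within array set 2, 6 without untreated specimen 1 or without untreated specimen 3, 11 without untreated specimen 2, 12 without trastuzumab specimen 1, 33 without trastuzumab specimen 2 and 3 without trastuzumab specimen 3. Other settings of the processing gave from 1 to 87 genes. Genes called lower numbered 12 of 87 with all arrays as values, 10 of 59 with specimen weights, and 1 of 22 with plain means, of 16 with only these groups, of 6 without untreated specimen 1, of 11 without untreated specimen 2 and of 33 without trastuzumab specimen 2.

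**Figure D1:**
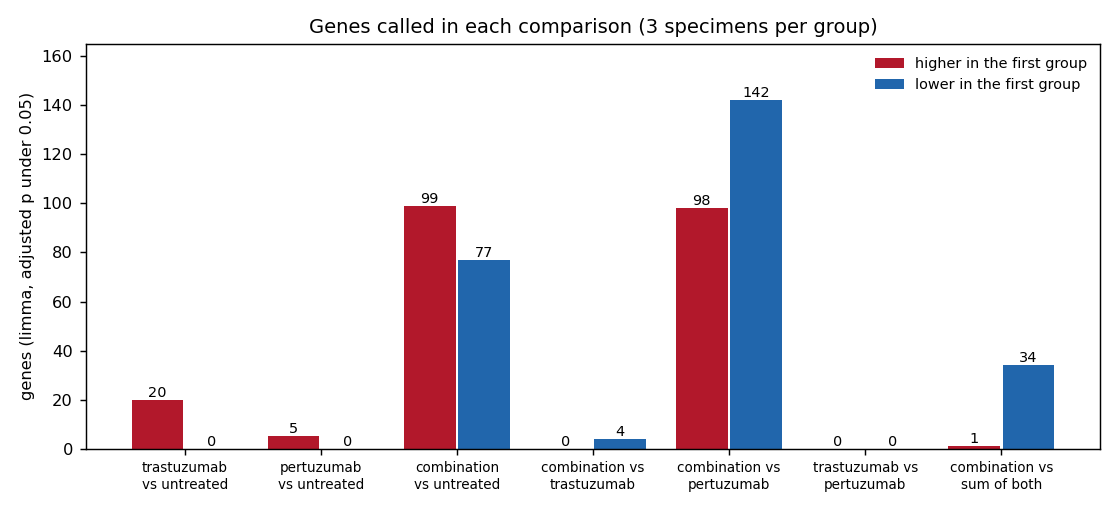
Number of genes called by limma at an adjusted p under 0.05 (vertical axis) in each of 7 comparisons (horizontal axis), with genes higher in the first group in red and lower in blue. The combination against untreated tumours gave 99 higher and 77 lower genes, trastuzumab alone 20 higher and pertuzumab alone 5 higher.

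Among gene lists fixed before the data were examined, synthesis of sterols and fatty acids was lower with trastuzumab by camera (median -0.29, adjusted p = 5.7e-10; adjusted p = 0.169 with an estimated correlation). All 21 measured members were negative. None fell over all genes and 7 fell adjusted over the list alone, among them INSIG1, which holds back sterol synthesis (-0.67 ± 0.15), HMGCS1, an early enzyme of the pathway (-0.63 ± 0.17), and SQLE, squalene epoxidase (-0.49 ± 0.15). Epithelial genes were higher (median 0.36, adjusted p = 1.3e-08; adjusted p = 0.169 with an estimated correlation), with 0 of 15 members called over all genes and 7 higher adjusted over the list alone, including CDH1, the adherens junction cadherin (0.65 ± 0.13), MUC16, the CA125 antigen (1.06 ± 0.28), and the tight junction gene CLDN7 (0.42 ± 0.13). Targets of FOXO transcription factors were higher (adjusted p = 7.1e-05; adjusted p = 0.29 with an estimated correlation), with 1 of 17 members higher over all genes (CDKN1A) and 4 adjusted over the list alone (CDKN1A, ERBB3, GADD45A at 0.53 ± 0.16 and FBXO32 at 0.51 ± 0.15).

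Genes of DNA replication and of mitosis were slightly lower with trastuzumab, by a median of -0.20 and -0.22 (adjusted p = 1.0e-07 and 1.3e-08). These calls gave adjusted p = 0.401 and 0.423 with an estimated correlation. All 27 replication members and 33 of 34 mitosis members were negative, as for DTL (-0.42 ± 0.12) and TPX2 (-0.35 ± 0.12), and none fell over all genes or adjusted over the list alone. Hypoxia and glycolysis genes were higher (median 0.28, adjusted p = 6.8e-04; adjusted p = 0.638 with an estimated correlation), with 0 of 24 members called either way. Their median was −0.01 without trastuzumab specimen 3, and the call was also lost without untreated specimen 3. HER family receptors and ligands were higher (adjusted p = 0.00805; adjusted p = 0.29 with an estimated correlation) with 0 of 10 members over all genes and 2 adjusted over the list alone, ERBB3 and NRG4 (0.48 ± 0.13). That call was lost without untreated specimen 3 (adjusted p = 0.0629) or trastuzumab specimen 3 (adjusted p = 0.103). The HER2 amplicon list was near the threshold (adjusted p = 0.0474; adjusted p = 0.401 with an estimated correlation), with 0 of 13 members called either way, and its call was lost without untreated specimen 1 or 3 and without trastuzumab specimen 2 or 3 (medians from 0.06 to 0.19). The 3 measured skin and keratinocyte genes were higher (adjusted p = 2.9e-04; adjusted p = 0.196 with an estimated correlation), with KRT5 called over all genes, KRT14 at 1.67 ± 0.49 higher adjusted over the list alone, and KRT10, abundant in skin, at 0.13 ± 0.15. Medians that moved by over 1.5 times were HER family 0.20 and hypoxia 0.42 without untreated specimen 1, FOXO targets 0.27 without specimen 2, and HER2 amplicon 0.06, HER family 0.06, mitosis -0.12 and hypoxia 0.18 without specimen 3. They were HER family 0.26 and sterol -0.18 without trastuzumab specimen 1, HER2 amplicon 0.10, replication -0.33 and hypoxia 0.59 without specimen 2, and HER2 amplicon 0.08, HER family 0.07, mitosis -0.13, hypoxia -0.01 and epithelial 0.23 without specimen 3.

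The other lists were not called with trastuzumab. Their adjusted p-values were 0.792 for ERK pathway output, 0.104 for cyclin-dependent kinase inhibitors, 0.848 for apoptosis regulators, 0.183 for unfolded protein and amino acid stress, 0.918 for ribosomal proteins, 0.877 for interferon-stimulated genes, 0.555 for antigen presentation, 0.555 for mesenchymal and TGF-beta response genes, 0.133 for fibroblast markers and 0.556 for leukocyte markers. The ERK list's median was 0.04 while its mean and test were negative, and the apoptosis list's median was -0.01 while its mean and test were positive.

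The second comparison set pertuzumab against no treatment. KRT16 and ANXA8 rose here too, 2.59-fold and 2.72-fold (1.37 ± 0.17 and 1.45 ± 0.18, n = 3 per group). SERPINA1, alpha-1-antitrypsin, rose 2.7-fold (1.44 ± 0.20) and MMP13, a collagenase, 1.92-fold (0.94 ± 0.14). XDH, xanthine dehydrogenase, rose at least 1.34-fold from a level not detected on any untreated array. KRT5 (1.77 ± 0.35, adjusted p = 0.127) and CDKN1A (0.54 ± 0.17) were not called, nor were ERBB2 (0.12 ± 0.19), ERBB3 (0.26 ± 0.14), EGFR (0.19 ± 0.20), CDKN1B (-0.09 ± 0.11), CCND1 (0.12 ± 0.20) and MKI67 (0.04 ± 0.19). No gene was called lower. The values nearest to a call were those of TSC22D3, a glucocorticoid-induced gene (-0.54 ± 0.13), of VCAN, a matrix proteoglycan (-0.54 ± 0.15), and of CLDN11, TXK and BNIPL (at least 1.05-fold, 1.06-fold and 1.19-fold lower), all 3 not detected on any pertuzumab array.

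In all, 5 genes were called with pertuzumab, all higher, with 576 of 10448 at an unadjusted p under 0.05, against about 5% by chance. For each of the 5, all 3 treated specimens lay above all 3 untreated ones, as for 468 of 10448 genes, against 5% by chance. In either direction the share of all genes was 10.6%, against 10% by chance. The count of called genes was 5 within array set 1 and 2 within array set 2. It was 3 without untreated specimen 3, without pertuzumab specimen 1 or without pertuzumab specimen 3, and 13 without pertuzumab specimen 2. With specimen weights it was 1767, of which 767 were higher and 1000 lower, while no other setting called a gene lower. The 4 genes called higher with both antibodies were SERPINA1 (probe ILMN_2338452), ANXA8 (ILMN_2095610), KRT16 (ILMN_2228162) and MMP13 (ILMN_1663873), where independent lists would share 0.00957 genes and simulated unchanged groups with the same controls, which give almost no calls, shared 0 on average. The 20 and 5 highest genes of these simulated groups shared 0.96 on average and at most 4. These were ranked genes and almost none was called, so whether shared controls alone bring 4 shared calls cannot be told.

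Epithelial genes were higher with pertuzumab (median 0.26, adjusted p = 3.9e-06; adjusted p = 0.169 with an estimated correlation). Of 15 members, 14 were positive and none was called over all genes or adjusted over the list alone, as for JUP, a desmosome and adherens junction protein (0.70 ± 0.21). The skin and keratinocyte list was higher (adjusted p = 1.1e-04; adjusted p = 0.196 with an estimated correlation), with 0 of 3 members called over all genes and KRT5 and KRT14 (1.36 ± 0.49) higher adjusted over the list alone, while KRT10 stood at 0.25 ± 0.15. ERK pathway output genes were higher (median 0.16, adjusted p = 0.00125; adjusted p = 0.401 with an estimated correlation), with 0 of 21 members over all genes and 1 adjusted over the list alone, the immediate early gene EGR1 (0.88 ± 0.19). Mesenchymal and TGF-beta response genes were higher (median 0.23, adjusted p = 0.0311; adjusted p = 0.458 with an estimated correlation), with 0 of 14 over all genes and 1 adjusted over the list alone, the transcription factor SNAI2 (0.83 ± 0.19). HER family receptors and ligands were higher (adjusted p = 0.0118; adjusted p = 0.309 with an estimated correlation), with 0 of 10 members either way. The ERK call was lost without untreated specimen 3 (adjusted p = 0.0509), the mesenchymal call without untreated specimen 1 or 2 or pertuzumab specimen 1 (lowest median 0.09), and the HER family call without untreated specimen 3 or pertuzumab specimen 2 or 3 (lowest median 0.05). Medians that moved by over 1.5 times were HER family 0.21 without untreated specimen 1, mesenchymal 0.09 without specimen 2, and HER family 0.05 and ERK output 0.05 without specimen 3. They were mesenchymal 0.11 without pertuzumab specimen 1, and skin 0.81 without specimen 3.

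The other lists were not called with pertuzumab. Their adjusted p-values were 0.689 for the HER2 amplicon, 0.236 for FOXO targets, 0.535 for DNA replication, 0.649 for mitosis, 0.848 for cyclin-dependent kinase inhibitors, 0.347 for apoptosis, 0.786 for hypoxia, 0.176 for sterol synthesis, 0.104 for unfolded protein stress, 0.701 for ribosomal proteins, 0.715 for interferon-stimulated genes, 0.0501 for antigen presentation, 0.811 for fibroblast markers and 0.618 for leukocyte markers. The kinase inhibitor and hypoxia lists had medians of -0.03 and -0.02 while their tests were positive.

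The third comparison set the combination against no treatment. TGFBI, a matrix protein induced by TGF-beta, fell 5.59-fold (-2.48 ± 0.37, n = 3 per group), and SPP1, osteopontin, fell 3.31-fold (-1.73 ± 0.37). The neutrophil chemokine CXCL8 (-1.49 ± 0.25), the caveolar protein CAV1 (-1.42 ± 0.30), the nicotinamide-methylating enzyme NNMT (-1.65 ± 0.20) and LCN2, lipocalin-2 (-1.36 ± 0.19), fell as well, as did ALPK2 (-2.05 ± 0.41), CFI (-1.46 ± 0.28), CLDN16 (-1.39 ± 0.24) and ANXA3 (-1.35 ± 0.24). KLK11 rose 6.26-fold (2.65 ± 0.28), ANPEP, aminopeptidase N, 4.88-fold (2.29 ± 0.45) and CHGA, a protein of secretory granules, 3.85-fold (1.95 ± 0.32). Further rises were those of the epithelial serine protease PRSS8 (1.73 ± 0.28), MUC16 (1.51 ± 0.28), neurotensin (NTS, 1.96 ± 0.40), the calcium pump ATP2C2 (1.69 ± 0.25), TM4SF4 (1.90 ± 0.43), GLYATL3 (2.20 ± 0.49) and C9orf152 (1.85 ± 0.35). ERBB3, the HER family member that pairs with HER2, rose 2.11-fold (1.08 ± 0.14, adjusted p = 0.00515), and CDKN1A rose 2.07-fold (1.05 ± 0.17). ERBB2 (0.25 ± 0.19), EGFR (-0.00 ± 0.20), CDKN1B (0.08 ± 0.11), CCND1 (-0.10 ± 0.20) and MKI67 (0.18 ± 0.19) were not called.

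In all, 176 genes were called with the combination, 99 higher and 77 lower, and 1477 had an unadjusted p under 0.05. For all 176 the 3 treated and 3 untreated specimens did not overlap in either direction, as for 1860 of all genes, against 10% by chance. The count was 153 within array set 1 and 104 within array set 2. It was 23 without combination specimen 1, 20 without combination specimen 2, 68 without untreated specimen 1 and 96 without untreated specimen 3, and 7 of the 30 called genes among those named or listed were called in every such fit.

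**Figure D2:**
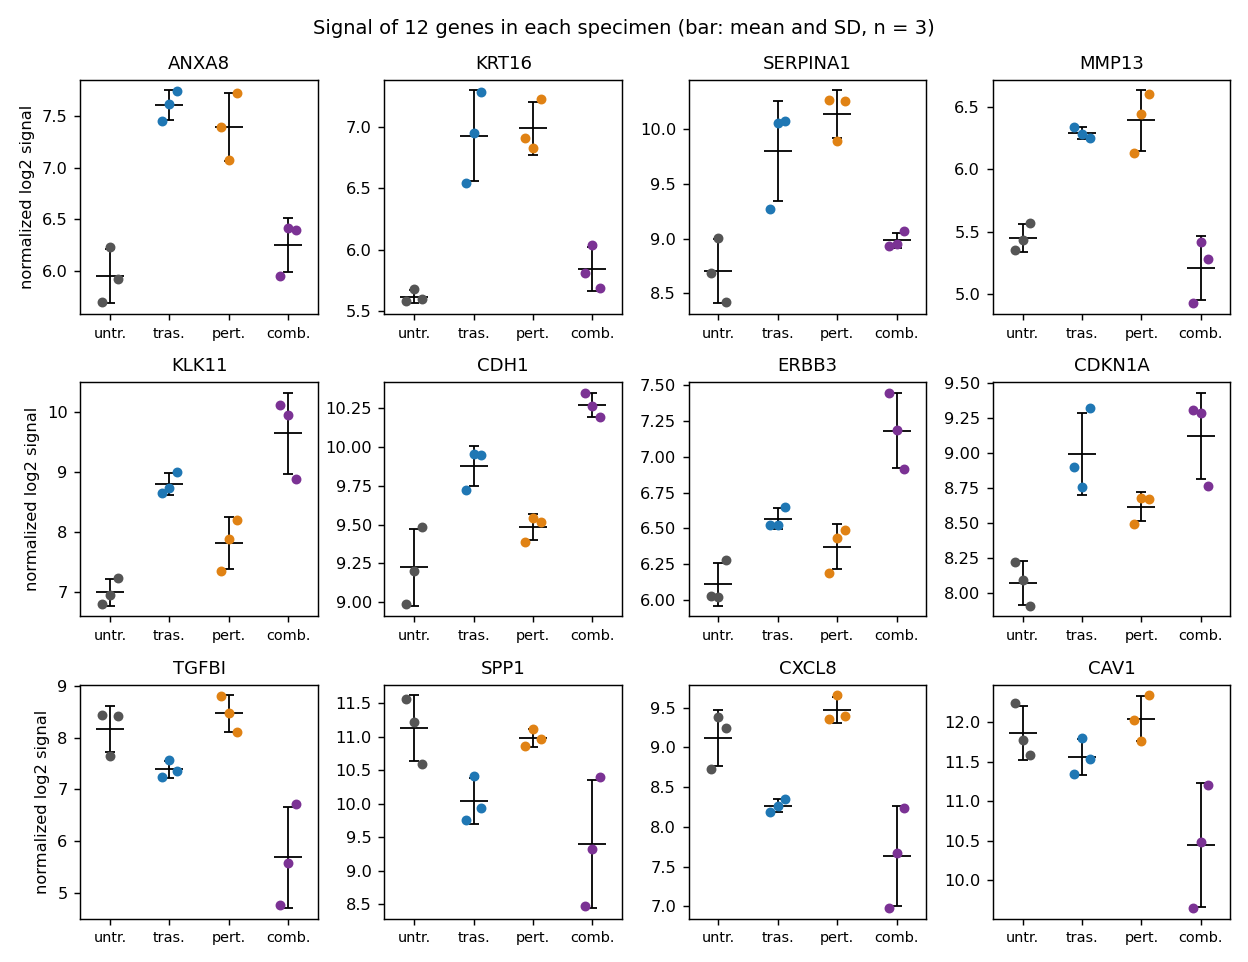
Normalized log2 signal (vertical axes) of 12 genes in each specimen of the untreated, trastuzumab, pertuzumab and combination groups (horizontal axes), with points for specimens and bars for the mean and SD of 3 specimens. KRT16 lay at a mean of 6.93 with trastuzumab and 6.99 with pertuzumab, against 5.62 untreated and 5.84 with the combination. TGFBI lay at 5.69 with the combination and 8.17 untreated.

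Epithelial genes were higher with the combination (median 0.42, adjusted p = 6.1e-07; adjusted p = 0.169 with an estimated correlation, and 0.0194 by fry). Of 15 measured members, 5 rose over all genes, and 8 rose and 1 fell adjusted over the list alone. CDH1 rose 2.07-fold (1.05 ± 0.13), and the tight junction claudins CLDN7 (0.90 ± 0.13) and CLDN3 (0.69 ± 0.11) and the mucin MUC16 rose with it. Mesenchymal and TGF-beta response genes were lower (median -0.34, adjusted p = 2.0e-05; adjusted p = 0.213 with an estimated correlation), with 3 of 14 lower over all genes and 6 adjusted over the list alone. These 3 were TGFBI, the matrix protein SPARC (-1.04 ± 0.18) and the actin-binding TAGLN (-1.20 ± 0.26), while ZEB1, a repressor of CDH1, stood at -0.59 ± 0.14 and was lower adjusted over the list alone.

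Sterol and fatty acid synthesis genes were lower (median -0.23, adjusted p = 2.9e-04; adjusted p = 0.401 with an estimated correlation), with INSIG1 (-0.68 ± 0.15) lower over all genes and 6 of 21 adjusted over the list alone. Interferon-stimulated genes were lower (median -0.38, adjusted p = 3.6e-05; adjusted p = 0.401 with an estimated correlation), with 25 of 27 members negative and IFITM1 (-0.95 ± 0.27) and SAMD9 (-0.60 ± 0.15) lower adjusted over the list alone, while ISG20, an exonuclease, rose over all genes (1.15 ± 0.25). Hypoxia and glycolysis genes were lower (median -0.44, adjusted p = 3.6e-04; adjusted p = 0.62 with an estimated correlation), with 0 of 24 called either way, as for LDHA (-0.37 ± 0.10). FOXO targets were higher (median 0.13, −0.01 with median scaling, adjusted p = 0.00805; adjusted p = 0.406 with an estimated correlation), with ERBB3 and CDKN1A higher over all genes and 4 of 17 higher and 2 lower adjusted over the list alone. The HER2 amplicon list was higher (median 0.25, adjusted p = 0.00129; adjusted p = 0.196 with an estimated correlation), with GRB7, the HER2-binding adaptor, higher over all genes (0.54 ± 0.13) and 3 of 13 adjusted over the list alone. GRB7 stayed called in 0 of 6 fits that left out a specimen and in 6 of 14 other settings. The hypoxia call was lost without untreated specimen 1 (adjusted p = 0.0706) and the FOXO call without untreated specimen 3 (adjusted p = 0.127). Medians that moved by over 1.5 times were FOXO targets 0.27 and interferon-stimulated -0.21 without untreated specimen 2, and HER2 amplicon 0.13 and FOXO targets 0.04 without specimen 3. They were hypoxia -0.26 and interferon-stimulated -0.20 without combination specimen 1, and FOXO targets 0.19 without specimen 2.

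The other lists were not called with the combination. The HER family list (adjusted p = 0.114) held the rise of ERBB3 and a value of -0.69 ± 0.18 for the ligand NRG1. The ERK list (adjusted p = 0.747) held the fall of CXCL8 and values of 0.69 ± 0.22 for DUSP6 and 0.47 ± 0.14 for SPRY4, feedback inhibitors of the pathway. The adjusted p-values of the rest were 0.139 for DNA replication, 0.535 for mitosis, 0.0669 for cyclin-dependent kinase inhibitors, 0.535 for apoptosis, 0.0665 for unfolded protein stress, 0.767 for ribosomal proteins, 0.715 for antigen presentation, 0.767 for fibroblast markers, 0.723 for leukocyte markers and 0.114 for skin genes.

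**Figure D3:**
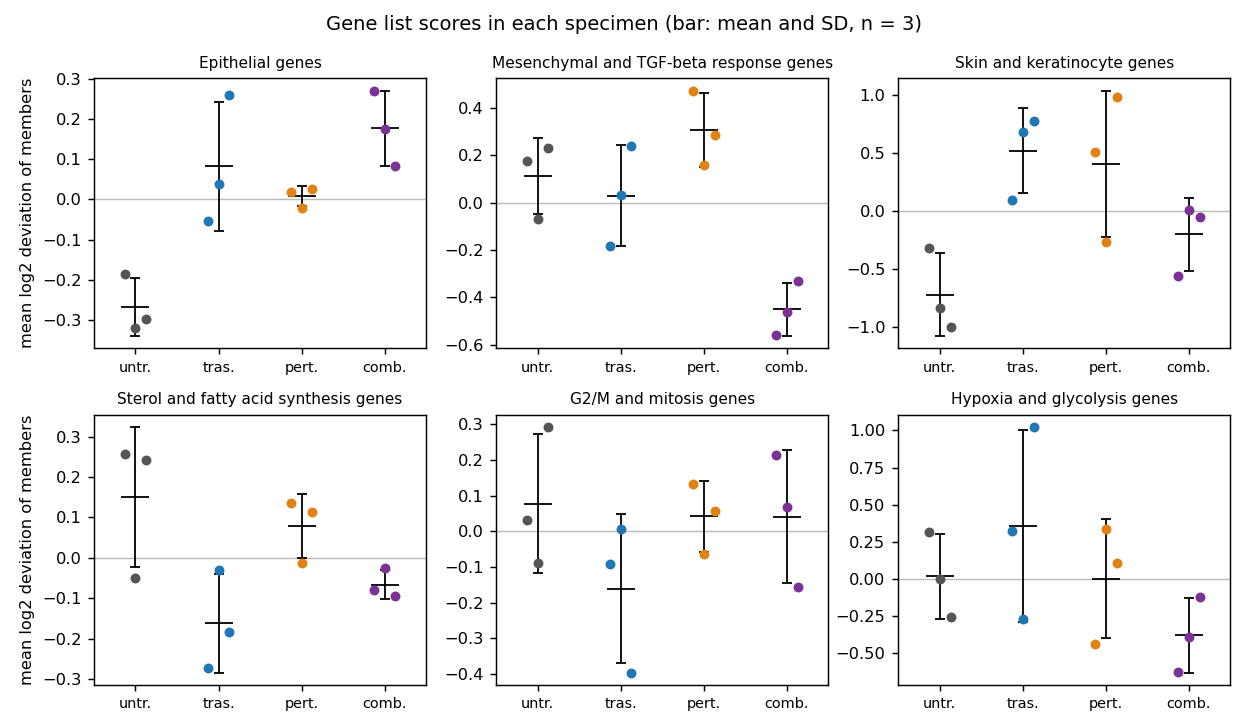
Mean log2 deviation of the measured members of 6 gene lists from their mean over all specimens (vertical axes) in each specimen of the 4 groups (horizontal axes), with points for specimens and bars for the mean and SD of 3 specimens. All 3 combination specimens lay above all 3 untreated ones for epithelial genes, while hypoxia genes in trastuzumab specimen 3 stood at 1.02 against 0.32 and -0.27 in the other specimens of its group.

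All 99 genes called higher with the combination had a positive value with trastuzumab (median 0.47) and 80 had one with pertuzumab (median 0.20). Of the 77 called lower, 76 were negative with trastuzumab (median −0.33) and 41 with pertuzumab (median −0.02). These genes were chosen by the same controls, and as many genes chosen alike in simulated unchanged groups gave the same sign in a mean of 90.8 (trastuzumab) and 90.6 (pertuzumab) of 99, at most 96, and of 71.3 and 70.9 of 77, at most 76. The pertuzumab counts of 80 and 41 lay below the lowest simulated ones, 84 and 65. The trastuzumab counts of 99 and 76 lay above and at the highest simulated ones. The simulated combination was unchanged, so its genes were chosen by the controls more than the real ones were. These ranges therefore do not tell how either antibody's change relates to that of the combination. Trastuzumab and the combination shared 5 called genes, CDKN1A, KLK11, LFNG, CLIC6 and LGALS4, and pertuzumab and the combination shared 0. The comparisons share the 3 untreated specimens, which alone gave simulated changes an r of 0.50 across genes, and 3 controls are too few to be split. Across genes, which are not independent, the observed r was 0.60 for trastuzumab with the combination, 0.28 for pertuzumab with the combination and 0.45 for the antibodies with each other. The covariances were 0.0317, 0.0133 and 0.0165 in the same order, against 0.0113 in the simulations. Independent lists would share 0.190 genes called higher for trastuzumab with the combination and 0.0474 for pertuzumab with the combination, and simulated groups, which give almost no calls, shared 0.01 on average. The highest 20 and 99 genes of the simulated groups shared 5.74 on average (at most 10), and the highest 5 and 99 shared 2.03 (at most 5). These simulated genes were ranked and almost none was called. They therefore cannot tell how many of the shared calls the shared controls bring.

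The fourth comparison set the combination against trastuzumab alone. ANXA8 (-1.35 ± 0.18), KRT16 (-1.08 ± 0.17) and MMP13 (-1.08 ± 0.14) were lower in the combination, 2.56-fold, 2.12-fold and 2.11-fold (n = 3 per group), and GPR15LG, a secreted ligand of GPR15, was at least 1.52-fold lower. These were the 4 called genes, and GLIPR1 came next (at least 1.28-fold lower, not detected on any combination array, adjusted p = 0.0528). There were 841 genes at an unadjusted p under 0.05. No gene was called higher, and the nearest values were 0.76 ± 0.14 for the peroxisomal oxidase ACOX2, 0.58 ± 0.11 for the efflux transporter SLC47A1, 0.56 ± 0.11 for ACSF2, 0.58 ± 0.12 for STARD10 and 0.94 ± 0.20 for TMT1B. Mesenchymal and TGF-beta response genes were lower (median -0.50, adjusted p = 1.6e-06; adjusted p = 0.29 with an estimated correlation), with 0 of 14 over all genes and 4 adjusted over the list alone, SNAI2 (-0.99 ± 0.19), TGFBI (-1.70 ± 0.37), THBS1 (-0.97 ± 0.22) and SPARC (-0.75 ± 0.18). Hypoxia genes were lower (median -0.74, adjusted p = 2.1e-13; adjusted p = 0.476 with an estimated correlation), with 0 of 24 over all genes and 13 adjusted over the list alone. Further camera calls were replication genes (median 0.19, −0.03 with median scaling) and mitosis genes (median 0.21) higher, and unfolded protein stress genes (median -0.23) and interferon-stimulated genes (median -0.33) lower, with adjusted p = 0.549, 0.501, 0.317 and 0.476 with an estimated correlation and no member called either way. The gene count was 3 within array set 1 and 0 within array set 2. It was 0 without trastuzumab specimen 3 or combination specimen 1, 7 without trastuzumab specimen 1, 23 without trastuzumab specimen 2, 38 without combination specimen 3 and 20 without combination array 2_2, a setting chosen after seeing the data. Genes called higher numbered 21 of 100 with all arrays as values, 23 of 86 with specimen weights, 1 of 13 with a trended, robust prior, 7 of 38 without combination specimen 3, 3 of 20 without combination array 2_2 and 1 of 23 without trastuzumab specimen 2. List calls were lost without trastuzumab specimen 3 (replication and mitosis). List medians over 1.5 times larger or smaller were replication 0.30 without trastuzumab specimen 2, and replication 0.09, mitosis 0.05, hypoxia -0.46 and mesenchymal -0.24 without specimen 3. They were replication 0.10, mitosis 0.11, hypoxia -0.48 and interferon-stimulated -0.19 without combination specimen 1, and unfolded protein stress -0.14 without specimen 3.

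The fifth comparison set the combination against pertuzumab alone. TGFBI was 6.87-fold lower in the combination (-2.78 ± 0.37, n = 3 per group), SERPINA3, an acute phase protease inhibitor, 4.42-fold (-2.14 ± 0.37) and CXCL8 3.58-fold (-1.84 ± 0.25). ALPK2 (-2.10 ± 0.41) and NNMT (-1.81 ± 0.20) were lower as well. The matrix proteoglycan EPYC was 5.85-fold higher (2.55 ± 0.49), CHGA 4.87-fold (2.28 ± 0.32), LEFTY1, a secreted antagonist of Nodal, 4.13-fold (2.05 ± 0.44), KLK11 3.56-fold (1.83 ± 0.28) and ENPP2, autotaxin, 3.48-fold (1.80 ± 0.35). CDH1 (0.79 ± 0.13) and ERBB3 (0.81 ± 0.14) were higher over all genes, and the immediate early genes EGR1 (-0.84 ± 0.19) and JUNB (-0.82 ± 0.16) were lower.

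In all, 240 genes were called between the combination and pertuzumab, 98 higher and 142 lower, with 1520 at an unadjusted p under 0.05. Mesenchymal and TGF-beta response genes were lower (median -0.65, adjusted p = 1.5e-08; adjusted p = 0.29 with an estimated correlation), with 5 of 14 lower over all genes and 9 adjusted over the list alone, among them THBS1 (-1.29 ± 0.22), SPARC (-0.97 ± 0.18) and TAGLN (-1.53 ± 0.26). Interferon-stimulated genes were lower (median -0.18, adjusted p = 2.4e-04; adjusted p = 0.477 with an estimated correlation), with IFITM1 (-1.14 ± 0.27), IFITM3 (-0.74 ± 0.18) and SAMD9 (-0.65 ± 0.15) lower over all genes and 4 lower and 1 higher of 27 adjusted over the list alone. ERK output genes were lower (median -0.25, adjusted p = 0.00951; adjusted p = 0.477 with an estimated correlation), with 3 of 21 lower over all genes and 6 lower and 3 higher adjusted over the list alone. Epithelial genes (median 0.16, −0.02 with median scaling) and the HER2 amplicon (median 0.23) were higher, and hypoxia (-0.39), unfolded protein stress (-0.19), sterol (-0.12) and antigen presentation genes (-0.10) were lower, with adjusted p = 0.477, 0.343, 0.506, 0.343, 0.477 and 0.501 with an estimated correlation. The gene count was 195 within array set 1 and 152 within array set 2, and with median scaling it was 299, of which 78 were higher and 221 lower. Specimen weights gave 732 higher and 634 lower. The count was 57 without combination specimen 1, 94 without combination specimen 2, 59 without pertuzumab specimen 1 and 79 without pertuzumab specimen 3. List calls were lost without pertuzumab specimen 1 (antigen presentation), pertuzumab specimen 2 (epithelial), combination specimen 1 (antigen presentation and epithelial) and combination specimen 2 (antigen presentation and epithelial). List medians over 1.5 times larger or smaller were hypoxia -0.59 without pertuzumab specimen 1, hypoxia -0.22 without specimen 2, and unfolded protein stress -0.11 without specimen 3. They were ERK output -0.15 and interferon-stimulated -0.08 without combination specimen 1, and interferon-stimulated -0.32 and antigen presentation -0.20 without specimen 3.

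The sixth comparison set trastuzumab against pertuzumab. No gene was called by limma (smallest adjusted p = 0.255), and 839 had an unadjusted p under 0.05. The smallest p-values belonged to GLIPR1 (-0.72 ± 0.12), LCN2 (-0.998 ± 0.19), TFPI2, an inhibitor of serine proteases (-0.89 ± 0.17), CXCL8 (-1.20 ± 0.25) and ADGRE1 (-0.74 ± 0.16) among those lower with trastuzumab, and to ZDHHC11 (0.66 ± 0.13), GPR15LG (0.55 ± 0.11), DAPL1 (0.93 ± 0.19), ZSWIM5 (0.57 ± 0.12) and GYG2 (0.62 ± 0.13) among those higher. By camera, replication (median -0.19), mitosis (-0.19), sterol synthesis (-0.27), ERK output (-0.13), mesenchymal (-0.21) and antigen presentation genes (-0.14) were lower with trastuzumab than with pertuzumab, and FOXO targets (0.17) and hypoxia genes (0.45) higher. In the order named these gave adjusted p = 0.477, 0.477, 0.343, 0.477, 0.477, 0.477, 0.477 and 0.6 with an estimated correlation, and the only member called adjusted over the list alone was CXCL8. Without trastuzumab specimen 2 the gene count was 17, and without pertuzumab specimen 2 it was 1. List calls were lost without trastuzumab specimen 1 (ERK output, antigen presentation and mesenchymal), trastuzumab specimen 2 (ERK output), trastuzumab specimen 3 (FOXO targets, mitosis and hypoxia) and pertuzumab specimen 1 (hypoxia). List medians over 1.5 times larger or smaller were sterol -0.16, antigen presentation -0.02 and mesenchymal -0.11 without trastuzumab specimen 1, ERK output -0.05 and hypoxia 0.77 without specimen 2, and ERK output -0.32, replication -0.10, mitosis -0.04 and hypoxia 0.02 without specimen 3. They were replication -0.13, hypoxia 0.22 and mesenchymal -0.13 without pertuzumab specimen 1, and ERK output -0.23 without specimen 3.

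The last comparison asked whether the combination's change differed from the sum of both single changes on the log2 scale (combination minus trastuzumab minus pertuzumab plus untreated). ANXA8 stood at -2.80 ± 0.26 and KRT16 at -2.46 ± 0.24, genes that both antibodies alone raised. With the combination ANXA8 stood at 0.30 ± 0.18 and KRT16 at 0.23 ± 0.17 against untreated, neither called. CLCA2 (-2.52 ± 0.33) and TNC, the matrix protein tenascin-C (-2.79 ± 0.40), were lower than the sum too, as was LY6D at −2.29 or less with its untreated level at the detection limit. Of 35 called genes 34 were lower, including SERPINA1 (-2.25 ± 0.29), MMP13 (-2.02 ± 0.20), the cytokine IL1A (-2.10 ± 0.37), SERPINB5, a serpin of epithelial cells (-2.39 ± 0.39), SNAI2 (-1.83 ± 0.27) and EGR1 (-1.40 ± 0.26), of which the first 4 were chosen after their values were seen. Across the 34 genes, which this sum selected, the median value was 0.78 with trastuzumab, 0.88 with pertuzumab and 0.06 with the combination, and 12 were called higher with trastuzumab, 5 with pertuzumab and 3 lower with the combination. The 1 gene higher than the sum was SLC47A1 (0.81 ± 0.15), with ACOX2 (0.94 ± 0.19), RTN1 (0.65 ± 0.13), ACSF2 (0.74 ± 0.15) and TMT1A (1.44 ± 0.32) next and not called.

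At an unadjusted p under 0.05 there were 677 such genes. The skin and keratinocyte list was lower than the sum (adjusted p = 1.7e-04; adjusted p = 0.29 with an estimated correlation), with 0 of 3 members over all genes and KRT5 (-2.50 ± 0.50) and KRT14 (-2.92 ± 0.70) adjusted over the list alone, while KRT10 stood at -0.12 ± 0.22. Mesenchymal and TGF-beta response genes were lower than the sum (median -0.62, adjusted p = 4.4e-07; adjusted p = 0.29 with an estimated correlation), with SNAI2 over all genes and 5 of 14 adjusted over the list alone. Hypoxia (-0.64), unfolded protein stress (-0.29), interferon-stimulated (-0.27) and ERK output genes (-0.12) were lower and mitosis (0.24), replication (0.21, −0.02 with median scaling) and sterol genes (0.15, −0.05 with median scaling) higher than the sum by camera, with adjusted p = 0.477, 0.29, 0.477, 0.501, 0.542, 0.565 and 0.506 with an estimated correlation. The gene count was 28 within array set 1 and 20 within array set 2. It was 17 without trastuzumab specimen 3, 20 without pertuzumab specimen 1, 19 without pertuzumab specimen 3, 19 without combination specimen 1, 22 without combination specimen 2 and 57 without combination specimen 3. With specimen weights it was 506, of which 204 were higher and 302 lower than the sum, so that the balance of 1 to 34 was not kept there. List calls were lost without untreated specimen 1 (replication, sterol and interferon-stimulated), untreated specimen 3 (ERK output, mitosis and sterol), trastuzumab specimen 1 (replication and sterol), trastuzumab specimen 3 (ERK output, replication, mitosis and sterol), pertuzumab specimen 2 (replication and sterol), combination specimen 1 (ERK output), combination specimen 2 (sterol) and combination specimen 3 (sterol). List medians over 1.5 times larger or smaller were ERK output -0.22 without untreated specimen 1, ERK output -0.02 and sterol 0.25 without specimen 2, and ERK output -0.19 and mitosis 0.11 without specimen 3. They were ERK output -0.22 and sterol 0.08 without trastuzumab specimen 1, ERK output -0.08 and replication 0.34 without specimen 2, and ERK output -0.17, replication 0.12, mitosis 0.11 and hypoxia -0.38 without specimen 3. They were replication 0.12 and interferon-stimulated -0.16 without pertuzumab specimen 2. They were ERK output -0.08, mitosis 0.15 and interferon-stimulated -0.14 without combination specimen 1.

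Markers of endothelium, leukocytes, red cells, skin and muscle were largely below detection on these human probes, while 12 of 15 fibroblast markers were detected on at least 5 arrays. The tumours grew in mice, and whether these human probes read RNA of any mouse cells in the tissue was not checked. CD68, AIF1, HBA2 and MYH4 were each detected on 23 arrays, and whether their signal was human or mouse cannot be told. Of the members with a named probe, 13 of 15 endothelial, 18 of 21 leukocyte, 6 of 7 red cell, 6 of 9 skin, 7 of 9 muscle and 3 of 15 fibroblast markers were detected on no array. The single tested members stood with trastuzumab, pertuzumab and the combination at -0.00, 0.51 and -0.39 for the endothelial PECAM1, -1.26, -0.64 and -1.17 for the haemoglobin gene HBA2, and -0.14, -0.03 and -0.11 for the muscle myosin MYH4, none called. Of the 3 leukocyte markers, AIF1 had values of -1.02 ± 0.60, -0.70 ± 0.60 and 0.40 ± 0.60. Of 12 measured fibroblast markers, the matrix gene FBLN1 rose with the combination (1.18 ± 0.22), 2 rose and 1 fell adjusted over the list alone, LUM at 1.27 ± 0.30 and MFAP5 at -1.26 ± 0.31, and the list's median was 0.01.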

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

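The tests of mouse skin, of specimens left out of the choice of genes and of single trastuzumab tumours in this part were chosen after the results were seen. The counts over other groupings of the specimens were planned. The departure of the combination from the sum of the single changes singled out 35 genes (limma, adjusted p under 0.05), of which the named ones were LY6D (−3.01 as fitted, and −2.29 or less with its untreated level, detected on no array, at the detection limit), ANXA8 (−2.80), TNC (−2.79), CLCA2 (−2.52), KRT16 (−2.46) and SLC47A1 (0.81). They stand here because the response to 1 antibody differed with and without the other by the test of that difference.

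The first pattern is that genes of basal and squamous epithelia and others, KRT16, ANXA8, CLCA2 and TNC among those named, were below the sum, with medians over the 34 genes below it of 0.78 with trastuzumab, 0.88 with pertuzumab and 0.06 with the combination. Of these, 24 were called lower in the combination than with pertuzumab and 4 than with trastuzumab, but the sum that selected them favours such differences. Whether the combination lay below each antibody was asked in specimens that took no part in the choice of genes. For each of the 81 ways to leave out 1 specimen per group, 34 genes were chosen by the smallest p below the sum without these 4 specimens. In the specimens left out, their median was lower in the combination than with trastuzumab (−1.41 to −0.03) and than with pertuzumab (−1.46 to −0.32) in 81 of 81, ways that share specimens. No untreated value enters these differences, so they cannot tell whether untreated tumours were low by chance. Among 100 drawn assignments of the 12 specimens to 4 groups, 2 gave as many genes, the real one (35) included, and the highest other gave 35. The share was under 0.05, but since another assignment reached the same count, chance was made less likely and not excluded. Mouse skin in the tissue pieces cannot be told apart by KRT10, abundant in skin, which stood at 0.25 ± 0.15 with pertuzumab and 0.13 ± 0.15 with trastuzumab, because human probes may not read mouse RNA, and 6 of 9 skin genes were detected on no array. A response of the cancer cells to each antibody, changed by the other, remains a hypothesis.

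The second pattern is the shift of hypoxia, replication and mitosis genes with trastuzumab. That trastuzumab specimen 3 alone carries it is consistent with the hypoxia values, whose median was −0.0079 without that specimen (adjusted p = 0.824, and from 7.3e-11 to 0.0629 without another trastuzumab or untreated specimen). For replication and mitosis genes this cannot be told apart, since their medians were −0.14 and −0.13 without it, with adjusted p = 6.8e-05 and 0.00114 by camera at the preset correlation but 0.519 and 0.693 with an estimated correlation (0.401 and 0.423 with all specimens). No other cause was tested.

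For the numbers of genes called between pairs of groups, 3 specimens against 3 make only 10 splits and no share under 0.05 can be had. As many genes as the real split, itself included, were called in 2 splits for trastuzumab (20 genes, highest other 819), 1 for pertuzumab (5 genes, highest other 0), 1 for the combination (176, highest other 0), 1 for combination against trastuzumab (4, highest other 0), 1 for combination against pertuzumab (240, highest other 0) and 10 for trastuzumab against pertuzumab (0, highest other 2). The split with 819 genes set untreated specimen 1 and trastuzumab specimens 2 and 3 against the rest, which points to a structure among these specimens other than the treatment. It follows no array set or label in the sources used here, and no biological explanation was tested.

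Combination array 2_2 had a mean signal of 365, against 208 to 246 for the other 4 arrays of its group. This was 1 such array in 84 groups of arrays tested over 21 measures, where chance alone gives about 1 in 20 groups.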

How the results depend on the processing

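The alternative without combination array 2_2 was chosen after seeing the data and all others were planned. Counts in each sentence follow the order trastuzumab, pertuzumab and combination against untreated (20, 5 and 176 genes as reported), combination against trastuzumab and against pertuzumab (4 and 240), trastuzumab against pertuzumab (0) and departure from the sum (35). Left unfiltered, the counts were 1, 0, 45, 0, 62, 0 and 10, and with probes detected on every array 7, 2, 93, 1, 167, 0 and 20, settings that test more or fewer probes. Median scaling in place of quantile normalization gave 69, 18, 192, 72, 299, 0 and 93. It shifted the median of all genes by −0.18 for combination against trastuzumab, −0.10 for combination against pertuzumab and −0.19 for the departure from the sum, and changes there are relative to these shifts. Quantile normalization without background correction gave 17, 4, 177, 2, 261, 0 and 39, and the deposited normalized values gave 17, 4, 173, 2, 260, 0 and 39. All arrays as values with a correlation within specimens gave 87, 35, 434, 100, 540, 9 and 96. Array set 1 alone gave 13, 5, 153, 3, 195, 0 and 28, and array set 2 alone 10, 2, 104, 0, 152, 0 and 20. Plain means of arrays gave 22, 5, 181, 6, 240, 0 and 36. A trended, robust prior gave 17, 5, 164, 13, 234, 0 and 32. Weights estimated per specimen gave 59, 1767, 1913, 86, 1366, 0 and 506, with weights from 0.34 to 4.49 and shares of higher genes that moved by over 10 points in 5 comparisons, given with these. Fits of only the groups compared gave 16, 4, 88, 9, 328 and 2. Without combination array 2_2 the counts that involve the combination were 217, 20, 303 and 33. What made the counts differ between settings was not tested.

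The specimen numbers did not pair the groups (4 of 18 same-number pairs of specimens had r over 0.1 across probes), and a fit with the specimen number as a block gave 13, 9, 93, 8, 147, 0 and 32 genes.

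Leaving out 1 specimen at a time gave 3 to 33 genes for trastuzumab, 3 to 13 for pertuzumab, 20 to 256 for the combination, 0 to 38 for combination against trastuzumab, 57 to 302 for combination against pertuzumab, 0 to 17 for trastuzumab against pertuzumab and 17 to 57 for the departure from the sum. These fits leave a group with fewer specimens and fewer degrees of freedom. The specimens that moved a count by over 1.5 times are named with each comparison.

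No called gene among those named or listed changed sign in any setting. With median scaling the medians of 5 list calls did, with the direction of the camera test unchanged, namely FOXO targets with the combination (−0.01), replication genes (−0.03) against trastuzumab, epithelial genes (−0.02) against pertuzumab, and replication (−0.02) and sterol genes (−0.05) for the departure from the sum. Of the values under alternatives of all genes named or listed, called or not, 5467 kept their side of the threshold, 224 passed it newly and 384 no longer passed. The first number includes uncalled genes that stayed uncalled, and the last is of called genes alone. Among the called genes named or listed, those called without each specimen in turn were 2 of 11 for trastuzumab, 2 of 5 for pertuzumab, 7 of 30 for the combination, 0 of 4 and 6 of 21 for the combination against trastuzumab and pertuzumab, and 6 of 8 for the departure from the sum. Of 21 list calls against untreated, 0 passed with an estimated correlation and 1 by fry, and 17 to 21 in the other settings, which called 18 to 24 lists in all. Genes near background, with signals close to the offset, have compressed differences, so that their folds may be understated.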

Other observations

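Genes in this part were chosen after their values were seen, and the tests of 3 further gene lists were as well. With the combination, further called genes were those of transcription factors of glandular epithelia, FOXA2 (0.99 ± 0.21, n = 3 per group) and FOXA3 (1.19 ± 0.22), of FOXJ1, which drives the formation of motile cilia (at least 1.64-fold), and of LGR5, a receptor of epithelial stem cells (1.47 ± 0.28), all higher. The epithelial sodium channel subunit SCNN1A (1.04 ± 0.17), P-cadherin (CDH3, 1.26 ± 0.26), the splicing factor ESRP1, which promotes epithelial isoforms (at least 1.04-fold), and DEPTOR, an inhibitor of mTOR (1.20 ± 0.27), rose too. The KIT ligand KITLG fell (-1.25 ± 0.16), as did the chemokine CXCL1 (at least 1.80-fold), the cytokine IL6 (at least 1.09-fold) and HMGA2 (at least 1.21-fold).

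Compared with pertuzumab alone, the combination had lower MMP1 (-0.84 ± 0.15), PLAU, urokinase (-1.10 ± 0.24), the HER3 ligand NRG1 (-1.14 ± 0.18) and HIF1A (-0.60 ± 0.12), and higher ESR1, the oestrogen receptor (0.57 ± 0.12), and LUM (1.73 ± 0.30).

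A hypothesis was that basal and squamous genes moved beyond the called genes. A list of 58 such genes was written after the called genes were seen, and the 14 measured members called in no comparison were tested with camera in limma and an estimated correlation. Their median was 0.38 with trastuzumab (adjusted p = 0.0436 over 5 tests, unadjusted 0.0174), 0.37 with pertuzumab (adjusted p = 0.0560, unadjusted 0.0336, not past the threshold) and −0.65 for the departure from the sum (adjusted p = 0.0436, unadjusted 0.00899). The list and its directions came from the called genes of the same specimens, and its members are correlated with each other (estimated at 0.23). These values are therefore no separate support for a shift wider than single genes, which remains a hypothesis.

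The same was asked with camera in limma of 13 uncalled glandular and secretory genes with the combination, whose median was 0.53 (adjusted p = 0.0664, unadjusted 0.0532), and of 16 uncalled NF-kB and inflammatory genes, whose median was −0.35 (adjusted and unadjusted p of 0.229). Neither passed.

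All 23 columns of the deposited normalized table hold, within 0.1% at each rank, 1 set of values in different orders. That set is 0.958 to 0.992 times the mean of the 23 sorted raw columns. A candidate explanation is that a further, nearly empty array entered the normalization, since the remainder for such an array did not fall, by more than a tolerance of 1e-06, at 99.4% of the ordered steps and reached at most 87.5, against a lowest maximum of 19018 among the arrays used. The array codes leave place for a second array of combination specimen 3, which was not analysed here.

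The combination group received 20 mg/kg of each antibody, and no group received the summed dose of 1 antibody, so that its values hold the larger amount of antibody as well as the pairing.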
